A study of Mus musculus with 10 samples.

How the data were processed

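RNA was measured in 10 mouse cell lines, 1 library each. The parental line is 4T1-hHER2, a mouse mammary carcinoma line that carries human HER2 and luciferase. The 9 derived lines fall into 3 groups of 3 by the tissue in their labels: fat pad tumour (primary), circulating tumour cells (CTC) and lung metastasis. Libraries are named by group and by the number in their title.

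The deposited tables hold estimated counts per gene and per transcript, not scaled to library size. HISAT2 2.1.0, StringTie 2.0.3 and DESeq2 1.26.0 on GRCm38 are named in the submitters' processing notes. StringTie shares reads among overlapping transcripts, so the deposited whole numbers are estimated counts. The annotation release is not given in the sources used here. All 141692 Ensembl transcript names of the transcript table occur in GENCODE M21, which was used for gene positions and overlaps. The use of strand in counting is not stated in the sources used here, so overlapping and antisense genes are reported as uncertain. The gene table has 72544 entries, of which 55418 carry a gene name and 17126 are assembled transcripts tied to no gene. The assembled transcripts took between 19.7% and 22.8% of the counts of a library. The total count per library was 79869760 to 97722716. In the transcript table, 1 entry was filled in 1 column only and was left out.

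Tests were run on the named genes alone, because a transcript tied to no gene cannot be named in a result. This choice was made after the tables had been examined and after a fit of all entries had been run, and its effect on the counts of genes is given among the alternatives. A low level of a named gene can therefore mean that its reads were counted under an assembled transcript. The test of each gene was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr at its defaults, all 10 libraries in 1 fit of 4 groups, and Benjamini-Hochberg adjustment at 0.05. After the filter, 19936 genes were tested. Where nothing differs, a share of about 0.05 of the genes or transcripts is expected at an unadjusted p under 0.05. The contrasts were metastasis against primary, CTC against primary, metastasis against CTC, any difference among these 3 groups, and the mean of the derived groups against parental. The parental line has 1 library, which is assumed to vary like the others and has no replicate. The common biological coefficient of variation was 0.606. Transcripts were tested in the same way, with 78270 tested. Levels are CPM, that is counts scaled to a common library size with TMM factors. Standard errors (SE) are on the log2 scale. They were derived from the test, as the absolute log2 change divided by the square root of its F statistic.

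Before the data were examined, 30 gene lists were fixed: 19 of pathways, 3 of RNA quality or stress and 8 of host cell types. The 29 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The rule for named genes, also fixed before, took genes that passed, had a mean log2 CPM of at least 1, a symbol that is not the name of a predicted gene, a clone or a pseudogene (ending in -ps), and groups that do not overlap. Where fewer than 3 passed in a direction, it took the 5 genes with the smallest p in that direction, reported as not passing. It also took up to 4 members of each list and Erbb2, Xist, Cdh1, Epcam, Vim and Ptprc. For the test of any difference it took the 10 genes with the smallest p. Genes outside this rule were chosen after their values were seen and are marked so.

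Some groups share numbers in their titles (5 and 7 in primary and metastasis, 3 in CTC and metastasis). Whether the numbers pair the lines was checked by correlating deviations from the group means over the genes. The 3 same-number pairs gave 0.319, 0.12 and 0.406, all above 0.1, against a median of -0.0495 over the other pairs, and 5 of 6 libraries correlated best with their own number. Some pairs with different numbers correlated more than any same-number pair, CTC 6 with metastasis 7 (0.506) and primary 8 with CTC 6 (0.43). In the alternatives with a block the numbers were treated as pairing the lines on this evidence from the values, since the labels do not say what a number stands for. The main fit does not use the numbers, so same-number lines count as independent in it. With the number as a random block, the estimated correlation of same-number lines was 0.531. CTC and primary lines share no number. The fit with the number as a fixed block uses the 9 derived lines and leaves 1 residual degree of freedom, so a call lost in it says little.

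The alternatives were other scalings, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with and without library weights, the number as a block, leaving out each derived line, and smaller sets of libraries. All entries of the gene table, assembled transcripts summed per locus, a robust spread and a fit of 2 groups were added after the data were examined. The gene tests of metastasis against primary and of derived against parental were tested on simulated data made from the real means and spreads, with 50 genes changed at each fold. For metastasis against primary, edgeR recovered 32% of the genes changed 4-fold, 78% of those changed 8-fold and 94% of those changed 16-fold, with 1 false call among 19936 genes. DESeq2 recovered 58%, 96% and 98%, with 69 false calls. For derived against parental, edgeR recovered 0% at 4-fold, 28% at 8-fold and 58% at 16-fold, with 1 false call. Neither comparison recovered a gene changed 2-fold with edgeR. The changed genes all had a mean log2 CPM of at least 1, so recovery of lower genes was not tested. For metastasis against primary a list shifted 4-fold was recovered by camera with an estimated correlation (adjusted p 0.000219), and 1 of 28 other lists was called with the preset correlation. The simulated libraries of same-number lines shared no deviation from their group, unlike the real ones, so recovery and false calls of genes with it were not tested. The simulated genes were drawn independently of each other. The real cholesterol synthesis list had an estimated correlation of 0.645 and the mitochondrially encoded list 0.817. The simulation thus cannot show recovery or false calls of lists at such correlations. Principal components were computed on the 1000 most variable genes. Groups of 3 against 3 can be split in 10 ways, and each split was fitted. For any difference among the 9 lines, 100 of 280 splits were drawn for genes and 40 for transcripts. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.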

Results

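RNA sequencing of 10 mouse mammary carcinoma lines gave between 79869760 and 97722716 estimated counts per library. The parental line, 4T1-hHER2, had 1 library. The 9 derived lines were grown out of NSG mice, an immunodeficient strain: primary 5, 7 and 8 from fat pad tumours, CTC 1, 3 and 6 from blood, and metastasis 5, 3 and 7 from lung. Per the labels, all 9 trace back to circulating tumour cells of mice that carried 4T1-hHER2 tumours. The p-values measure only the spread between these lines.

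Mouse Erbb2, the gene of the endogenous receptor, was at 34.8 CPM in the parental library. It was at 45.8 ± 11 CPM (SD, n = 3) in primary, 40.6 ± 14 CPM (SD, n = 3) in CTC and 50.7 ± 8.9 CPM (SD, n = 3) in metastasis lines. The human HER2 insert has no entry in a mouse annotation and was not analysed here. Xist stayed at or below 0.17 CPM in each library. Of the markers of host cells, Ptprc, carried by blood cells, reached 0.23 CPM, and the fibroblast collagens Col1a1 and Col3a1 reached 2.32 and 0.33 CPM. The most abundant marker was Gsn at 383 CPM (primary 7) on the fibroblast list, Mertk at 19.3 CPM on the macrophage list, Eng at 195 CPM (metastasis 5) on the endothelial list and S100a8 at 0.82 CPM on the neutrophil list. It was Itga2b at 6.94 CPM on the red cell and platelet list and Foxj1 at 3.62 CPM on the lung epithelial list. On the adipocyte list it was Plin4 at 4.31 CPM, and on the skeletal muscle list Tnni2 at 2.73 CPM (parental 1). In the parental library the other markers were at 195 (Gsn), 0 (Mertk), 102 (Eng), 0.4 (S100a8), 2.88 (Itga2b), 0.28 (Foxj1) and 0.17 CPM (Plin4).

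The first principal component held 49.2% of the variance. CTC 3 (60.9), metastasis 3 (59.6), metastasis 5 (53.2), CTC 1 (50.9) and primary 5 (21.8) scored above 0. Metastasis 7 (-16.9), CTC 6 (-37.6), primary 7 (-43.9), primary 8 (-65.4) and parental 1 (-82.6) scored below 0. Each derived group thus had lines on both sides. Over all genes, the median correlation of libraries was 0.943 within a group and 0.945 between derived groups.

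**Figure D1:**
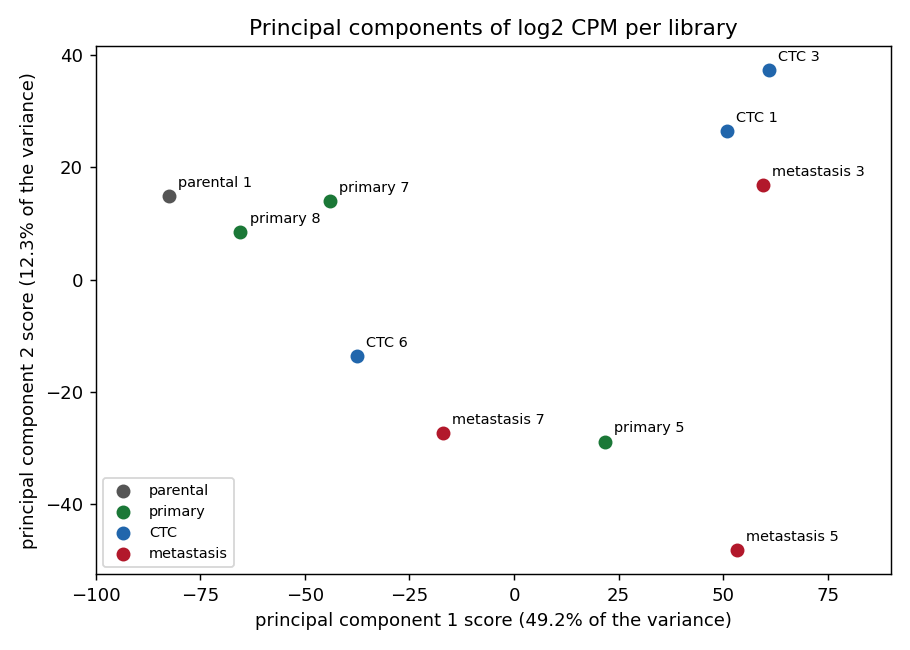
Scores of the 10 libraries on the first 2 principal components of log2 CPM, with 1 point per library coloured by group. The horizontal axis (49.2% of the variance) runs from parental 1 at -82.6 to CTC 3 at 60.9, and each derived group has lines on both sides of 0.

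Metastasis against primary asks which genes differ between lines from lung metastases and lines from fat pad tumours. Pelo, which encodes a factor that rescues stalled ribosomes, was at 0.665 ± 0.115 CPM (SD, n = 3) in metastasis and 6.68, 7.92 and 9.2 CPM in the 3 primary lines (mean 7.93). S100a6, a calcium-binding protein gene, was at 238 ± 53.5 CPM (SD, n = 3) in metastasis and 763 ± 153 CPM (SD, n = 3) in primary lines. Acap1 was at 8.25 ± 1.02 CPM (SD, n = 3) in metastasis and 47.3 ± 13.5 CPM (SD, n = 3) in primary lines. Trps1, which encodes a GATA-type repressor, was at 65.7 ± 13.9 CPM (SD, n = 3) in metastasis and 22.1 ± 5.78 CPM (SD, n = 3) in primary lines. None of these passed the test. Pelo had a log2 change of -3.57 (SE 0.35) and an adjusted p of 0.053 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and it shares exons with Gm10734 and Gm49395. The other named genes that were lower without passing were Acap1 (-2.52, SE 0.34), Postn (-8.84, SE 1.37), Kifc5b (-2.11, SE 0.33) and S100a6 (-1.68, SE 0.27), as log2 changes. Those that were higher without passing were Zscan25 (3.16, SE 0.64), Mxd4 (3.19, SE 0.66), Nipsnap2 (1.76, SE 0.37), Trps1 (1.57, SE 0.33) and Cpq (2.79, SE 0.63). edgeR called 0 of 19936 genes, with 1652 (8.3%) at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 135. The 1652 became 2900 without primary 5, 946 without primary 7, 935 without primary 8 and 853 without metastasis 5. The groups did not overlap for 2720 genes (13.6%, where chance gives 10%). Without primary 5, edgeR called 1 gene, Afdn (log2 change -4.11), chosen here after its value was seen. With the number as a random block, which pairs the lines, limma-voom called 2 genes, Pelo and Acap1. With the number as a fixed block edgeR called 0 genes in the fit of the derived lines (1460 at an unadjusted p under 0.05) and 0 in the fit of the 2 groups alone (1334). A low level of a named gene can be due to reads counted under an assembled transcript.

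**Figure D2:**
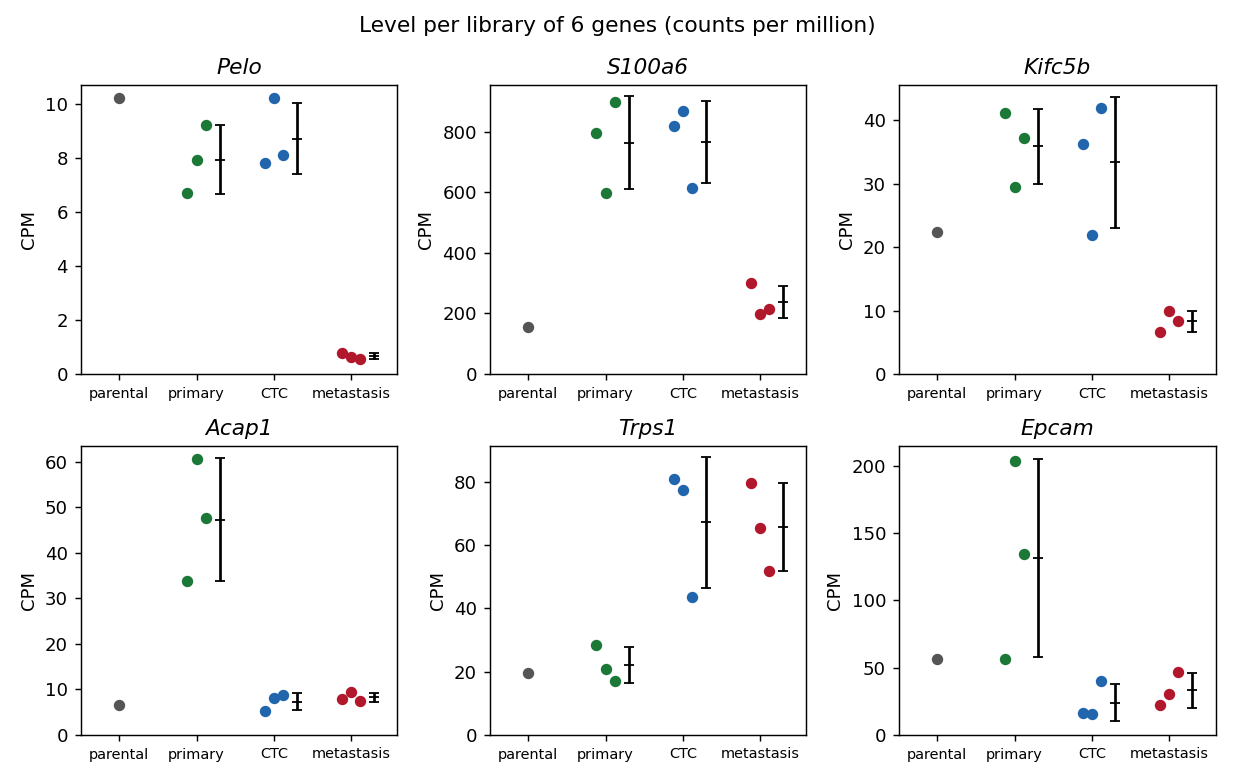
Level in CPM of Pelo, S100a6, Kifc5b, Acap1, Trps1 and Epcam, with 1 point per library by group, and the mean with its SD (n = 3) as a bar beside each derived group. Pelo lies between 6.68 and 10.2 CPM outside the metastasis lines and between 0.573 and 0.794 CPM in them.

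Camera with the preset correlation called the lists of the cell cycle and of epithelial adhesion lower in the metastasis lines. Neither list passed adjustment with an estimated correlation or with fry. All 33 tested members of the cell cycle list were lower (median log2 change -1.12), with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 1.22e-12, estimated-correlation p 0.13). Of 26 epithelial adhesion and keratin genes, 2 were higher and 24 lower, with 0 called over all genes and 3 adjusted over the list alone, Krt7, Cldn3 and Epcam (camera adjusted p 1.06e-06, estimated-correlation p 0.0959). All 13 mitochondrially encoded genes were higher, with 0 called over all genes and 11 adjusted over the list alone (camera adjusted p 4.38e-08, estimated-correlation p 0.108). This list and the next were fixed as lists of RNA quality or stress. Mitochondrial genes took 2.34% to 3.14% of the named-gene counts in the metastasis lines and 1.07% to 2.22% in the other libraries. Whether RNA quality differs between the groups was not tested apart from these lists. Of 16 transcripts without a poly-A tail, mostly histone genes, 2 were higher and 14 lower, with 0 called over all genes and 5 adjusted over the list alone (camera adjusted p 3.22e-08, estimated-correlation p 0.0358, 0.519 after adjustment, where the call is lost). Their mean log2 level was -1.37 in metastasis 5 and -1.21 in metastasis 7, but -0.22 in metastasis 3, near primary 7 (-0.07). These 4 lists were called without each derived line in turn. The groups overlapped for the epithelial list, whose mean log2 level in metastasis 7 (0.45) was above that in primary 5 (-0.02). The groups overlapped too for the lists of interferon-stimulated genes, MHC class I and oxidative phosphorylation. Of 30 interferon-stimulated genes, 2 were higher and 28 lower (camera adjusted p 0.00409, estimated-correlation p 0.384), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without primary 7 (0.869) or metastasis 5 (0.0507). Of 19 ERBB and MAPK genes, 6 were higher and 13 lower (camera adjusted p 0.00423, estimated-correlation p 0.0112, 0.324 after adjustment, where the call is lost), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without metastasis 7 (0.0756). Of 27 nuclear genes of oxidative phosphorylation, 5 were higher and 22 lower (camera adjusted p 0.0341, estimated-correlation p 0.457), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without primary 7 (0.0635), primary 8 (0.623), metastasis 5 (0.11) or metastasis 3 (0.386). Of 17 MHC class I genes, 13 were higher and 4 lower (camera adjusted p 0.039, estimated-correlation p 0.275), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without primary 5 (0.0759), primary 8 (0.227), CTC 6 (0.0565) or metastasis 5 (0.519). The other 21 lists had camera adjusted p of 0.202 to 0.901. Without metastasis 5 camera called 5 lists. With the number as a block, which pairs the lines, MHC class I (0.0571) and oxidative phosphorylation (0.968) were not called. With an estimated correlation 0 of the 29 lists passed adjustment. The test fry called 1, the ERBB and MAPK list (fry adjusted p 0.0352), and did not call the cell cycle or epithelial list (fry adjusted p 0.298 for each).

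**Figure D3:**
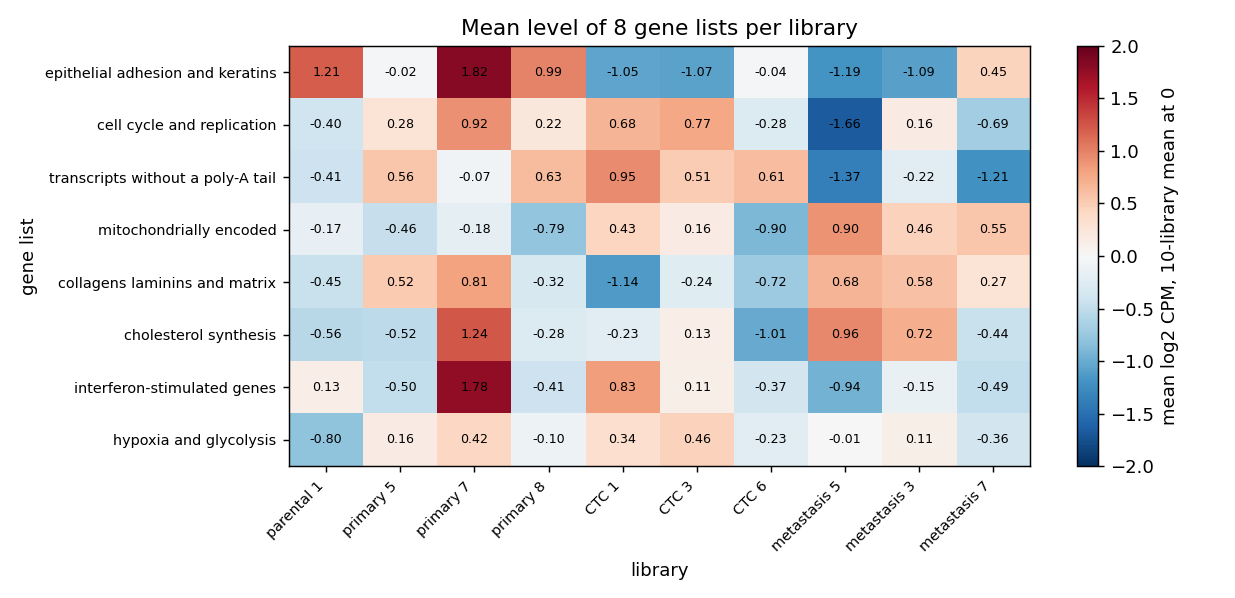
Mean log2 CPM of the tested members of 8 gene lists in each of the 10 libraries, with the mean over the libraries at 0. The cell cycle list lies between -1.66 and 0.16 in the metastasis lines and between 0.22 and 0.92 in the primary lines.

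CTC against primary asks which genes differ between lines from circulating tumour cells and lines from fat pad tumours. Epcam, an epithelial adhesion gene, was at 24 ± 13.6 CPM (SD, n = 3) in CTC and 131 ± 73.7 CPM (SD, n = 3) in primary lines. Acap1 was at 7.29 ± 1.86 CPM (SD, n = 3) in CTC lines, and Trps1 at 67.2 ± 20.6 CPM (SD, n = 3). Slc40a1, the iron exporter gene, was at 0.85 ± 0.284 CPM (SD, n = 3) in CTC and 7.93 ± 3.33 CPM (SD, n = 3) in primary lines. None passed the test. The smallest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.451, for Acap1 (log2 change -2.70, SE 0.34). The other named genes that were lower without passing were Postn (-8.17, SE 1.32), Slc40a1 (-3.22, SE 0.52), Zbtb20 (-3.98, SE 0.65) and Afdn (-3.45, SE 0.59). Those that were higher without passing were Trps1 (1.61, SE 0.33), Rn7sk (1.30, SE 0.29), Ercc6l2 (3.17, SE 0.72), Nipsnap2 (1.59, SE 0.36) and Mxd4 (2.75, SE 0.65). edgeR called 0 of 19936 genes, with 809 (4.1%) at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 69. The 809 became 1824 without primary 5, 489 without primary 7, 462 without CTC 1, 527 without CTC 3 and 1982 without CTC 6. The groups did not overlap for 1426 genes (7.2%, where chance gives 10%).

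Among the lists, epithelial adhesion and keratin genes were lower in the CTC lines, with 4 of 26 higher and 22 lower, 0 called over all genes and 1 adjusted over the list alone, Epcam (camera adjusted p 8.3e-08, estimated-correlation p 0.0673). It was called without each derived line in turn. Its mean log2 level in CTC 6 (-0.04) was near that in primary 5 (-0.02) and above CTC 1 (-1.05) and CTC 3 (-1.07). Of 26 matrix genes, 9 were higher and 17 lower, with 0 called over all genes and 1 adjusted over the list alone, Postn (camera adjusted p 0.00975, estimated-correlation p 0.132), and the list was not called without primary 5 (0.118) or CTC 6 (0.175). Of 23 cholesterol synthesis genes, 3 were higher and 20 lower, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 0.0118, estimated-correlation p 0.395), and the list was not called without primary 7 (0.898) or CTC 6 (0.413). Of 25 genes of the amino acid and ER stress response, 7 were higher and 18 lower, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 0.0201, estimated-correlation p 0.242), and the list was not called without primary 5 (0.118), primary 8 (0.141), CTC 1 (0.104) or CTC 3 (0.208). The other 25 lists had camera adjusted p of 0.0642 to 0.943. With an estimated correlation 0 lists passed adjustment, and fry called 0. The mean log2 levels of the matrix, cholesterol synthesis, and amino acid and ER stress lists overlapped between the groups. With the number as a block camera called 8 lists, but CTC and primary lines share no number, so this fit compares them only through the metastasis lines. It did not call cholesterol synthesis (0.135) or the amino acid and ER stress response (0.26). Without primary 7, and without the block, camera called 7 lists.

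Metastasis against CTC asks which genes differ between lines from lung metastases and lines from circulating tumour cells. Pelo fell, from 8.70 ± 1.31 CPM (SD, n = 3) in CTC to 0.665 ± 0.115 CPM (SD, n = 3) in metastasis lines. It was the 1 gene called of 19936, with a log2 change of -3.71 (SE 0.35) and an adjusted p of 0.0408 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Pelo (ENSMUSG00000042275.9) lies on chromosome 13 from 115088355 to 115090186 of GRCm38, inside the span of Itga1, and shares exons with Gm10734 and Gm49395, so its counts are uncertain. The call was lost without each of the 9 derived lines in turn, with adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment from 0.0767 (without primary 5) to 0.347 (without metastasis 7). It was not called with the number as a block, which pairs the lines (adjusted p 1 by the same edgeR test with Benjamini-Hochberg adjustment). That fit has 1 pair between these groups and 1 residual degree of freedom, so a lost call there says little. Over its 23 alternatives the log2 change of Pelo stayed between -4.03 and -3.58, and the adjusted p (edgeR, limma-voom or DESeq2, each with Benjamini-Hochberg adjustment) ran from 4.15e-26 to 1. Without CTC 3, 1 other gene was called, Rpl36a-ps2, a pseudogene chosen after its values were seen. Named genes that were higher without passing included Scaf11 (1.66, SE 0.29), B4galnt4 (2.25, SE 0.46), mt-Atp6 (1.25, SE 0.29) and Porcn (2.06, SE 0.52), as log2 changes. Those that were lower without passing included S100a6 (-1.69, SE 0.27), Kifc5b (-2.01, SE 0.33), Rn7sk (-1.22, SE 0.29) and Rmrp (-1.71, SE 0.44). In all, 656 genes (3.3%) had an unadjusted p under 0.05, limma-voom called 1 gene and DESeq2 called 27. The 656 became 370 without metastasis 5 and 1015 without metastasis 3. The groups did not overlap for 1651 genes (8.3%, where chance gives 10%).

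All 16 tested transcripts without a poly-A tail were lower in the metastasis lines, with 0 called over all genes and 8 adjusted over the list alone (camera adjusted p 1.01e-21, estimated-correlation p 0.00422, 0.122 after adjustment, where the call is lost). All 33 cell cycle genes were lower, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 1.61e-19, estimated-correlation p 0.0733). All 13 mitochondrially encoded genes were higher, with 0 called over all genes and 1 adjusted over the list alone, mt-Atp6 (camera adjusted p 1.13e-06, estimated-correlation p 0.139). This list and that of transcripts without a poly-A tail were fixed as lists of RNA quality or stress. Of 26 matrix genes, 22 were higher and 4 lower, with 0 called over all genes and 3 adjusted over the list alone, Col1a2, Col5a2 and Bgn (camera adjusted p 4.67e-06, estimated-correlation p 0.0435, 0.386 after adjustment, where the call is lost). These 3 are near the floor, with at most 1.2, 1.13 and 1.54 CPM in any library. All 4 tested lung epithelial markers were also higher without the list being called (camera adjusted p 0.058). They are near the floor too, with at most 3.14 CPM for Napsa and 1.92 CPM for Ager in any library. Foxj1 had 10 counts in metastasis 3 and Sftpb 6 counts in metastasis 7, and both had 0 in the other metastasis lines and in the CTC lines. Of 12 fibroblast markers, 7 were higher and 5 lower (mean log2 change 1.5, median 0.46, camera adjusted p 0.781, estimated-correlation p 0.614), with 0 called over all genes and 0 adjusted over the list alone. All 23 cholesterol synthesis genes were higher, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 6.82e-05, estimated-correlation p 0.26). The 5 lists called so far in this comparison were called without each derived line in turn. Some lines stood apart: the mean log2 level of the cholesterol list in metastasis 7 (-0.44) was below that in CTC 1 (-0.23) and CTC 3 (0.13), and that of the cell cycle list in metastasis 3 (0.16) was above that in CTC 6 (-0.28). Of 30 interferon-stimulated genes, 2 were higher and 28 lower (camera adjusted p 0.000294, estimated-correlation p 0.309), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without CTC 1 (0.172). Of 26 hypoxia and glycolysis genes, 7 were higher and 19 lower (camera adjusted p 0.0361, estimated-correlation p 0.185), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without CTC 1 (0.231), CTC 3 (0.23) or metastasis 7 (0.202). Of 27 nuclear genes of oxidative phosphorylation, 3 were higher and 24 lower (camera adjusted p 0.046, estimated-correlation p 0.482), with 0 called over all genes and 0 adjusted over the list alone, and the list was not called without primary 7 (0.0595), CTC 1 (0.125), CTC 6 (0.708), metastasis 5 (0.184) or metastasis 3 (0.714), nor with DESeq2 size factors (0.0559). The other 21 lists had camera adjusted p of 0.058 to 0.974. With an estimated correlation 0 lists passed adjustment, and fry called 0. With the number as a block, which pairs the lines, camera called 3 lists: cell cycle (2.25e-08), transcripts without a poly-A tail (1.32e-05) and matrix (0.0307). That fit holds 1 pair between these groups and 1 residual degree of freedom. It did not call interferon-stimulated genes (0.262), hypoxia and glycolysis (0.0812), oxidative phosphorylation (0.421), cholesterol synthesis (0.179) or mitochondrially encoded genes (0.262). Without CTC 1 camera called 5 lists.

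Any difference among the 3 groups was asked in 1 test. Pelo, Acap1, Postn, Afdn, Slc40a1, Zbtb20, S100a6, Kifc5b, Scaf11 and Platr16 had the smallest p. Platr16, a non-coding RNA that overlaps Gm13230, was at 56.5 ± 7.03 CPM (SD, n = 3) in primary, 25.2 ± 4.06 CPM (SD, n = 3) in CTC and 22.5 ± 3.63 CPM (SD, n = 3) in metastasis lines. Afdn, a gene of cell junctions, was at 170 CPM on average in primary, 15.6 CPM in CTC and 13.4 CPM in metastasis lines. edgeR called 0 of 19936 genes, with 1037 (5.2%) at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 121. The 1037 became 1851 without primary 5, 600 without primary 7, 678 without primary 8, 1633 without CTC 6 and 608 without metastasis 5. The smallest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.114, for Pelo. Without primary 5 it called 1 gene, Afdn (adjusted p 0.0262 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2.45e-08 to 1 over the alternatives for Afdn). With the number as a random block, which pairs the lines, limma-voom called 1 gene, Pelo, and with the number as a fixed block edgeR called 0 (1002 at an unadjusted p under 0.05).

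Derived against parental asks what differs between the 9 lines from mice and the line they came from. Ftl1-ps1 was at 0 counts in the parental library and at 53.2 to 111 CPM in the derived lines, so it was at least 1250-fold higher in each against a floor of 3 counts in the parental library. Gm47428 was at 29.3 CPM in the parental library and 0.17 to 0.45 CPM in the derived lines. Mir692-3 fell from 159 counts to 1 count in each derived line, and Gm12978 from 137 counts to 1 count in each. These 4 genes were the ones called of 19936, with adjusted p of 0.0011 for Ftl1-ps1 and 0.000932 for the other 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 4 fall outside the rule for named genes and were chosen after their values were seen. Their log2 changes were -6.60 (SE 0.45) for Gm47428, -7.18 (SE 0.46) for Mir692-3 and -6.96 (SE 0.49) for Gm12978. Gm47428 and Mir692-3 each overlap Ftl1-ps1 on chromosome 13 (Ftl1-ps1 from 74399694 to 74407346), and Gm12978 is a pseudogene that overlaps Gm12992, so all 4 are uncertain. Ftl1 itself, the ferritin light chain gene, was at 2275 CPM in the parental library and 2377 to 4831 CPM in the derived lines. In all, 2059 genes had an unadjusted p under 0.05, limma-voom called 24 genes and DESeq2 called 610. The 2059 became 3160 without CTC 6. The lone parental library is assumed to vary like the others, without a replicate. In the fits of each library against the rest, given under other observations, primary 7 had more calls than the parental library. The number of calls alone thus does not set the parental library apart. In these fits the parental library did have the most genes at an unadjusted p under 0.05. It also had the lowest score on the first principal component (-82.6).

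Fas, a death receptor gene, was at 62.1 CPM in the parental library and 5.8 to 14.8 CPM in the derived lines. It did not pass (log2 change -2.96, SE 0.35, adjusted p 0.0556 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) but was called without metastasis 5 (adjusted p 0.0247 by the same edgeR test with Benjamini-Hochberg adjustment, and 1.4e-06 to 0.238 over the alternatives for Fas). It was also called with upper-quartile factors (5 genes called), the stricter filter, the fit of 2 groups, limma-voom and DESeq2. Postn, a matrix gene, was at 36.6 CPM in the parental library, 8.59 to 19.4 CPM in the primary lines and at most 0.091 CPM in the other derived lines. It did not pass (log2 change -7.15, SE 0.89, adjusted p 0.0634 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) but was called without metastasis 7 (adjusted p 0.0495 by the same edgeR test with Benjamini-Hochberg adjustment, and 2.02e-08 to 0.615 over the alternatives for Postn). Myo5a did not pass (log2 change -5.20, SE 0.86) and was called without primary 8 (adjusted p 0.00115 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and up to 0.464 over the alternatives for Myo5a). These 3 fits each called 1 more gene, Gm3435, Ston2 and Cnot8 in this order, chosen after their values were seen. Mga (-2.44, SE 0.37) and Zfp65 (-3.01, SE 0.52) were also lower without passing. Virma (2.68, SE 0.38), Stat6 (2.98, SE 0.45), Grwd1 (2.45, SE 0.39), Slc18b1 (5.41, SE 0.88) and Rnmt (2.92, SE 0.50) were higher without passing. Vim, the vimentin gene, was at 301 CPM in the parental library and 584 to 4750 CPM in the derived lines and did not pass (3.07, SE 1.17).

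Of 27 nuclear genes of oxidative phosphorylation, 3 were higher and 24 lower in the derived lines, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 0.0015, estimated-correlation p 0.269). Of 26 epithelial adhesion and keratin genes, 6 were higher and 20 lower, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 0.00776, estimated-correlation p 0.249). Of 26 hypoxia and glycolysis genes, 19 were higher and 7 lower, with 0 called over all genes and 1 adjusted over the list alone, Tpi1 (camera adjusted p 0.00776, estimated-correlation p 0.104). These 3 lists were called without each derived line in turn. Of 27 inflammatory genes, 9 were higher and 18 lower, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p 0.0169, estimated-correlation p 0.13), and the list was not called without metastasis 7 (0.0938). The other 25 lists had camera adjusted p of 0.0924 to 0.877. With an estimated correlation 0 lists passed adjustment, and fry called 0.

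Tested per transcript, 53 of 78270 transcripts were called for derived against parental, 25 higher and 28 lower. Of these, 24 are annotated transcripts of 23 genes, including all 4 genes called above, and 29 are assembled transcripts. No gene had called transcripts in opposite directions, but Myo5a alone had more than 1 called transcript, so this says little. Opposite moves of transcripts that were not called were not counted. A transcript of Myo5a (ENSMUST00000123128) was at 46.4 CPM in the parental library and at most 0.03 CPM in the derived lines, with an adjusted p of 0.000568 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. edgeR called 0 transcripts for metastasis against primary, CTC against primary, metastasis against CTC and any difference. In this order 4969 (6.3%), 3204 (4.1%), 3280 (4.2%) and 3709 (4.7%) had an unadjusted p under 0.05. The 4969 became 3162 without primary 8, and the 3204 became 4989 without CTC 6. limma-voom called 9, 6, 0 and 9 transcripts for these comparisons. DESeq2 was not run on transcripts. Without metastasis 3, edgeR called 1 transcript for any difference. For derived against parental it called 25 transcripts without primary 5, 25 without primary 7, 21 without primary 8, 22 without CTC 1, 22 without CTC 3 and 29 without CTC 6. It called 23 without metastasis 5, 23 without metastasis 3 and 25 without metastasis 7.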

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

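The tests of the first principal component and the test of interferon genes for H2-D1 were chosen after the result was seen, as was the count of similar drops in other libraries. The splits of the libraries and the other tests were chosen before.

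Over the 9 derived lines, 135 measures were checked for a line far from the others, and 5 were found, where chance gives 6.8. Myo5a was at 31 CPM in primary 8 and at 1.49 to 3.19 CPM in the others. Zfp65 was at 1.29 CPM in primary 7 and at 3.02 to 6.25 CPM in the others. Oasl1, an interferon-stimulated gene, was at 2.46 CPM in metastasis 5 and at 17.4 to 122 CPM in the others. Psmb8, an immunoproteasome gene, was at 31.6 CPM in primary 8 and at 67.8 to 134 CPM in the others. Itga6, an integrin gene, was at 88.5 CPM in metastasis 7 and at 169 to 284 CPM in the others. The parental library, which was not part of this check, was near the line found for Oasl1 (3.29 CPM), Psmb8 (37.1 CPM) and Itga6 (97.8 CPM). It was not near it for Myo5a (155 CPM) and Zfp65 (33.5 CPM).

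Outside the named genes, 11 assembled transcripts had 0 counts in the parental library and at least 10 CPM in all 9 derived lines, and 46 had the reverse. Among assembled transcripts above 50 CPM in any library, 25.9% were at 0 in another, against 0.3% of named genes. The count of a named gene is the sum of its annotated transcripts, so these shares compare single transcripts with whole genes.

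The first principal component put lines of each group on both sides of 0. Fibroblasts of the host would bring collagens, and the highest level of Col1a1 or Col3a1 in any library was 2.32 CPM, which argues against them as its main source. Pdgfra, also on the fibroblast list, went the other way and followed the component. It was at 58.1 to 269 CPM in primary 5, CTC 1, CTC 3, metastasis 5 and metastasis 3, and at 4.05 to 11.3 CPM in the other libraries. A contribution of fibroblasts therefore stays open. An exact permutation test of the groups over the 9 lines gave p = 0.254, which leaves the stage of origin open. That test does not use the shared numbers. Metastasis scored above primary for number 5 (53.2 and 21.8) and number 7 (-16.9 and -43.9), and just below CTC for number 3 (59.6 and 60.9). Same-number lines lay closer together than under reshuffled numbers (exact permutation p = 0.0185, one-sided), which is consistent with a shared origin of same-number lines. What a number stands for is not given in the sources used here.

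H2-D1, a class I antigen gene chosen after its values were seen, was at 1255 CPM in metastasis 5 and at 22.3 to 97.2 CPM in the other libraries. Host cells as its main source are argued against, since of 79 markers under 1 CPM elsewhere the highest was 5.67 CPM in metastasis 5. That bound leaves out markers seen in other lines. Among these, Pdgfra (269 CPM), Pdgfrb (18.7 CPM) and Dcn (12.4 CPM) were highest in metastasis 5, while Gsn (126 CPM) was not. The fibroblast (1.3) and adipocyte (1.73) lists were also highest in metastasis 5. The adipocyte value rests on 3 tested genes, the most abundant being Plin4 at 4.31 CPM. On the fibroblast list Lum, Dpt, Fap, Thy1 and Mfap5 were at 0 CPM in metastasis 5. These markers go both ways, so a share of host cells stays open. Reads moved from other class I genes are argued against, since these rose by 476 CPM in sum, and so is an interferon response, since the interferon-stimulated list was at -0.94, the lowest of the 10 libraries. Reads counted under an assembled transcript in the other lines may contribute: 1 assembled transcript met the bound set beforehand, with 55.8 CPM in metastasis 5 and at least 885 CPM elsewhere. Its position is not given in the sources used here, and the same drop was seen for 1 transcript in the parental library and for 0 in the other 8, so this explanation stays open.

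DESeq2 called 135 genes for metastasis against primary where edgeR called 0, with 1652 at an unadjusted p under 0.05 and 0 by limma-voom. Of the 135, 13.3% had overlapping groups, but a gene high in a single line can have groups that do not overlap, so this leaves such genes open. In simulated data without changed genes DESeq2 made up to 47 calls, 34.8% as many, and in the simulated data with 200 changed genes it made 69 false calls. The first lies between the bounds set beforehand and the second above the upper one, so calls made by chance stay open. For CTC against primary the simulated calls were 84.1% of the 69 made, and for metastasis against CTC 174.1% of the 27 made.

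With 3 lines against 3 there are 10 splits, too few for a share under 0.05. For metastasis against primary, edgeR called 0 genes (1652 at an unadjusted p under 0.05, DESeq2 135, limma-voom 0) and at most 1 in another split, so 10 of 10 splits gave as many. DESeq2 called 135 genes and at most 1207 in another split (2 of 10 gave as many), transcripts gave 0 and at most 1 (10 of 10), and lists 8 and at most 11 (3 of 10). For CTC against primary, edgeR called 0 genes (809 at an unadjusted p under 0.05, DESeq2 69, limma-voom 0) and at most 1 in another split (10 of 10). DESeq2 called 69 and at most 1840 (3 of 10), transcripts gave 0 and at most 3 (10 of 10), and lists 4 and at most 7 (8 of 10). For metastasis against CTC, edgeR called 1 gene and at most 6 in another split (3 of 10). DESeq2 called 27 and at most 717 (5 of 10), transcripts gave 0 and at most 1 (10 of 10), and lists 8 and at most 8 (2 of 10). For any difference among the 3 groups, edgeR called 0 genes (1037 at an unadjusted p under 0.05, DESeq2 121, limma-voom 0) and at most 239 in another of 100 splits, so 100 gave as many. Transcripts gave 0 and at most 5 in another of 40 splits, so 40 gave as many. Where the real count is 0 each split gives as many by construction, so these shares say nothing on chance.

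The splits that called the most genes with DESeq2 point to a structure of the lines other than the groups. For metastasis against primary it was primary 5, metastasis 5 and metastasis 3 against the rest, for CTC against primary it was primary 5, CTC 1 and CTC 3, and for metastasis against CTC it was CTC 1, CTC 3 and metastasis 3. Each puts numbers 1, 3 and 5 against 6, 7 and 8, apart from metastasis 5 in the last. Among splits that part as many same-number pairs as the real one, DESeq2 called at most 18 genes for metastasis against primary (135 in the real one) and at most 39 for metastasis against CTC (27 in the real one). The splits that part fewer pairs called up to 1207 and 717, but 1 that parts no pair (primary 5, primary 8 and metastasis 5) called 12. CTC against primary has no same-number pair, and a split there called 1840 against 69 in the real one, so the pairs alone do not account for the structure. edgeR called 0 genes in the first 2 of these splits and 6 in the last, with 3643, 4197 and 2695 at an unadjusted p under 0.05, the highest of their comparisons.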

How the results depend on the processing

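All entries of the gene table, assembled transcripts summed per locus, the robust spread and the fit of 2 groups were chosen after the data were examined, as was the use of named genes alone. A single gene counts as reversed only where it is called before or after the change, and none was.

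For metastasis against primary edgeR called 0 genes (1652 at an unadjusted p under 0.05, limma-voom 0). The stricter filter gave 1 (Pelo), DESeq2 135 (47 higher, 88 lower), the number as a random block 2 (Pelo and Acap1; 0 as a fixed block), and leaving out 1 line 0 to 1 (Afdn, without primary 5). For CTC against primary 0 (809 unadjusted, limma-voom 0) became 69 with DESeq2 and 2 with library weights (Acap1 and Postn), and stayed 0 without each line. For metastasis against CTC the 1 call became 27 with DESeq2 and 0 with no filter, the replicate block, only the groups compared, all entries, entries per locus and the robust spread. Leaving out 1 line gave 0 to 1, where the 1, without CTC 3, was Rpl36a-ps2, chosen after its values were seen. Pelo was called in 8 of 23 alternatives. For any difference 0 (1037 unadjusted, limma-voom 0) became 121 with DESeq2, 1 with library weights and 1 with the random block (Pelo in both), and 0 to 1 without 1 line (Afdn, without primary 5).

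For derived against parental the 4 calls became 610 with DESeq2, 24 with limma-voom, 59 with library weights, 42 with all entries, 17 per locus and 8 in the fit of 2 groups. They were 4 to 6 without 1 line, and the same 4 genes were among them each time. The 4 genes were also among the 42 and the 17, 3 of them among the 24 of limma-voom, and 2 among the 3 called with the stricter filter. The cause of these changes was not tested.

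Transcripts called for derived against parental numbered 53, 323 with limma-voom and 21 (without primary 8) to 29 (without CTC 6) when 1 line was left out. limma-voom called 9 for metastasis against primary, 6 for CTC against primary and 9 for any difference, where edgeR called 0 (4969, 3204 and 3709 unadjusted). Leaving out 1 line gave 0 for the pairwise comparisons and 0 to 1 for any difference, 1 without metastasis 3.

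Lists called numbered 8, 4, 8 and 4 for the comparisons in the order metastasis against primary, CTC against primary, metastasis against CTC and derived against parental. With an estimated correlation they numbered 0, 0, 0 and 0, and with fry 1, 0, 0 and 0. With the replicate block metastasis against CTC, with 1 pair, had 3 lists, and CTC against primary, with no pair, had 8. For metastasis against primary it no longer called MHC class I (0.0571) and oxidative phosphorylation (0.968). Among genes the replicate block, with 1 residual degree of freedom, changed only the call of Pelo for metastasis against CTC. Leaving out 1 line gave 5 (without metastasis 5) to 8, 3 to 7 (without primary 7), 5 (without CTC 1) to 10, and 3 to 5 lists. Erbb2 in the parental library was 34.8 CPM, and 33.1 CPM by total count. In the simulated data edgeR recovered 0% of 2-fold changes for metastasis against primary and for derived against parental, and DESeq2 6% and 10%.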

Other observations

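The tests of single libraries were chosen after the comparison with the parental library was seen, and the genes below after their values were seen.

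Genes at the high end of the first principal component were off or low in some lines and abundant in others. Aqp1, a water channel gene, was at 131 to 408 CPM in primary 5, CTC 1, CTC 3, metastasis 5 and metastasis 3, and at 0.1 to 22.9 CPM in the other 5 libraries. Slc14a1, a urea transporter gene, was at 157 CPM in CTC 1 and 0 in the parental library and in primary 8. Lgr6, a receptor of R-spondins, was at 306 CPM in metastasis 5 and 0.01 CPM in the parental library. At the low end, Krt19 was at 262 CPM in primary 8 and 0.77 CPM in CTC 3, and Adam12 at 96.6 CPM in primary 8 and 0.04 CPM in metastasis 5. Spp1, which encodes osteopontin, was at 45.9 CPM in the parental library and 305 to 9545 CPM in the derived lines.

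Fitting each library in turn as a lone group against the other 9 called 8 genes for the parental library, 10 for primary 7, 5 for CTC 6, 5 for metastasis 5, 3 for CTC 3, 2 for primary 5, 1 for primary 8, 1 for metastasis 7 and 0 for CTC 1 and metastasis 3. These counts by edgeR had 543 genes for CTC 1 and 269 for metastasis 3 at an unadjusted p under 0.05, and no other tool was run on them. Ndufa13 was listed at 0 in 7 of the 10 libraries.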
